A study of Rattus norvegicus and Drosophila melanogaster with 15 samples.

How the data were processed

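Each gut library came from 30 dissected Drosophila melanogaster guts taken 5 days after eclosion, with Malpighian tubules and trachea taken off, from flies kept at 29 °C. IEC-6 is a non-transformed epithelial cell line from rat small intestine, and the cultures were kept at 37 °C. RNA sequencing libraries were made from total RNA, and the series design names 3 biological replicates in each of 5 groups, 15 libraries in all. The control guts and cells are labelled as wild type, and whether they carried a control construct is not given in the sources used here, so an effect of the constructs themselves on the changes against control was not examined. Whether those replicates were separate crosses or separate cultures is not given, so the p-values measure the spread between these libraries only.

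The authors deposited FPKM values, fragments scaled to gene length and to the size of the library, in a table with a block for each species. HTSeq and DESeq2 are named per the submitters' processing notes, without versions or roles, with the genome builds dm6 for the fly and rn6 for the rat. The aligner, the gene annotation and the strand setting are not given in the sources used here, so overlapping or antisense genes, and near-identical copies, may share reads. The fly block lists 11629 genes, of which none is 0 in every library, and the rat block lists 17277, of which 326 are. Of the fly symbols, 10603 matched the gene annotation of the same assembly, and of the rat symbols, 15574 matched a RefSeq table of another assembly, from which no coordinate was taken. In the fly block 5 symbols have the form of calendar dates and were left unnamed.

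Depth is not stated, but the low values are whole multiples of a step per gene. Among 1892 low fly genes 93.6% and among 3631 low rat genes 94.7% had values that were whole multiples in every library, within 0.01 of a read. The steps gave relative depths. With annotated exon lengths they gave scaling totals of 32.3 to 36.4 M fragments for the gut controls and 34.0 to 35.8 M for the RNAi guts, as estimates (M, mega). For the IEC-6 libraries relative depth ran from 0.957 to 1.083 of control replicate 1, and the absolute depth is unknown.

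Groups were taken from the labels. Values were analysed as log2(FPKM + 1), so that fold changes of genes with low values are understated. Genes with a mean of at least 1 FPKM over the libraries of a fit were tested, with Liph kept at any level. The 6 gut libraries were fitted together, and the 9 IEC-6 libraries were fitted together with contrasts of each hairpin against the control and of sh2 against sh1. Each fit used limma 3.58.1 in R 4.3.3 with a mean-variance trend, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are from limma. The targeted genes were also compared by exact permutation tests, two-sided, which cannot give less than 0.1 for 3 against 3. Gene lists, 35 for the fly and 31 for the rat, were written before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares the members with the other tested genes. In the gut the median gene stood 0.25 higher on the log2 scale, so a list can pass as lower there without falling. No list passed with the estimated correlation. With fry in its directional form no sh1 list passed either, the lowest adjusted p being 0.0839, that of interferon response among them. For sh2 the fry adjusted p was 0.00126 for DNA replication, 0.0129 for mitosis and 0.000299 for DNA repair. In the gut it was 0.00162 for oxidative phosphorylation, 0.0224 for progenitor markers and 0.0478 for serine proteases of digestion. The gut lists of the cell cycle, at 0.167, of other digestive and neutral lipases, at 0.184, and of enteroendocrine markers, at 0.275, did not pass. Neither did fat body and yolk, at 0.13, hemocyte markers, at 0.459, Malpighian tubule markers, at 0.954, and fatty acid oxidation, at 0.412. After the data were seen, 17 list symbols were respelled as the table writes them.

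The genes named in the gut are CG6295 and its neighbouring lipase genes, and the 10 genes with the largest rise and the 10 with the largest fall. These had an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the 3 and 3 libraries. For IEC-6 the same rule took up to 10 rises and 10 falls shared by both hairpins, ranked by the smaller change, and 5 rises and 5 falls of sh2 against sh1. Genes without a symbol were passed over, and 1 gene that the rule names is not reported here. Up to 4 members with the smallest adjusted p are named from each list described, for IEC-6 by the larger of the adjusted p-values of the hairpins. The fits were tested on simulated data with 200 changed genes. Of changes of 1 on the log2 scale, 86% were recovered for the gut comparison over 7841 genes, and 92% and 96% for sh1 and sh2 over 10638 genes. Of changes of 0.585, 42% were recovered for the gut, 50% for sh1 and 48% for sh2. False calls numbered 12 of 175 for the gut, 12 of 182 for sh1 and 7 of 179 for sh2. The simulated genes varied independently and without a shift of the median gene, unlike the gut data.

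Alternatives were another pseudocount, no filter or a filter at 5 FPKM, TPM scaling, median centring, quantile normalization, moderation without the trend, a minimum log2 fold change of 1, the replicate number as a block, fits of only the groups compared, and leaving out each library in turn. Because each hairpin was compared with the same control libraries, chance overlap was simulated 100 times with unchanged groups. The controls, 3 libraries, are too few to be split into parts of at least 2 libraries.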

Results

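RNA sequencing was used to ask how lowering a lipase gene changes gene expression in the intestine of the fruit fly and in an intestinal epithelial cell line of the rat. In the fly, guts with RNA interference against CG6295, a gut-enriched lipase gene, were compared with control guts (3 libraries each). In rat IEC-6 cells, a pair of short hairpin RNAs against Liph, the gene of lipase H, were each compared with control cells (3 libraries in each of the 3 groups). Between 7475 and 7955 genes reached 1 FPKM in a gut library and between 10430 and 10659 in an IEC-6 library. The 50 genes with the highest values held 38.0% to 41.2% of the summed FPKM in the control guts and 30.9% to 35.0% in the RNAi guts.

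CG6295 was lowered to 47.1% of the control level in the RNAi guts. It lies on chromosome 3R, from 27005899 to 27007055 on the minus strand of the dm6 assembly, in a group of related lipase genes. Control libraries held 4300, 4978 and 3784 FPKM and RNAi libraries 2591, 1480 and 2082, so that the mean fell from 4354 ± 599 to 2051 ± 556 FPKM (SD, n = 3 each). The log2 fold change was -1.11 (SE 0.22, limma adjusted p = 0.0171), and the exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Of the neighbouring genes, CG17192 fell by 1.08 and CG6296 by 0.84 on the log2 scale (adjusted p = 0.0241 each). CG6277, at -0.47, and CG6283, at -0.10, did not pass. CG6283 stood at 0.002 under TPM scaling and at 0.10 without RNAi replicate 2. CG6271 and CG17191 were below the filter on low values. The sequence of the RNAi construct is not given in the sources used here, so a match to these neighbours was not examined. CG17192 lost its call without control replicate 2 (adjusted p = 0.0822), RNAi replicate 2 (0.0593) or RNAi replicate 3 (0.0648), and CG6296 without the same libraries (0.0791, 0.0593 and 0.0749). The call for CG6295 was lost without control replicate 2 (adjusted p = 0.0787) and without RNAi replicate 3 (adjusted p = 0.0633).

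**Figure D1:**
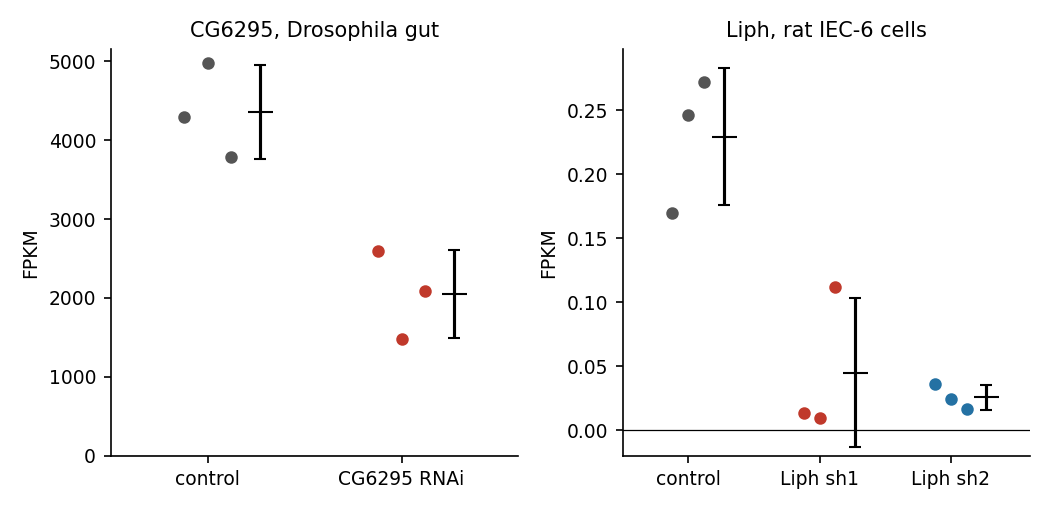
FPKM of the targeted genes in each library, CG6295 in the fly gut on the left and Liph in IEC-6 cells on the right; each dot is a library, and the bar beside it is the mean ± SD of 3. The RNAi guts lie between 1480 and 2591 FPKM, below all 3 controls, and Liph is at 0.112 FPKM in sh1 replicate 3, above the other libraries of both hairpins.

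Among the genes with the largest changes in the CG6295 RNAi guts, GstD2, DptA and tobi rose and PGRP-SC1b and a pair of Jonah serine protease genes fell. The largest rises were in CG34040, from 11.9 ± 8.61 to 242.5 ± 110 FPKM (log2 fold change 4.39), and in GstD2, a glutathione S-transferase, from 2.34 ± 1.83 to 64.5 ± 38.1 FPKM (4.17). Next came obst-H, of a family of chitin-binding proteins (3.47), CG13905 (3.04), and tobi, an alpha-glucosidase gene known as a target of brain insulin (3.04). CG14545 (3.01), the antimicrobial peptide gene DptA (2.94), CG16762 (2.76), CG43773 (2.76) and CG18446 (2.66) completed the 10. The largest fall was in PGRP-SC1b, an amidase that degrades bacterial peptidoglycan, from 249.0 ± 71.6 to 43.6 ± 20.2 FPKM (log2 fold change -2.57). It was followed by the Jonah serine proteases Jon66Cii (-1.94) and Jon65Aii (-1.90), and by CG4563 (-1.86), CG4830 (-1.79), CG42821 (-1.79), the heat shock gene Hsp70Bb (-1.75), CG9259 (-1.74), CG32751 (-1.73) and the cytochrome P450 gene Cyp6a14 (-1.67). Adjusted p-values of these 20 genes ran from 0.00471 to 0.0471 and their standard errors from 0.16 to 0.61, and all 20 kept their call after median centring. PGRP-SC1b and Hsp70Bb have near-identical copies, among which the counting could split reads.

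In all, 2540 of 7841 tested genes were called, 2131 higher and 409 lower in the RNAi guts. The median gene stood 0.25 higher on the log2 scale, and relative to that shift, after median centring, 1201 genes were called, 372 higher and 829 lower. As chosen after the data were seen, 781 genes were called with the same sign both ways, 372 higher and 409 lower. No overlap between the 3 and 3 libraries was found for 52.1% of the tested genes, where chance gives 10%. The count rested on single libraries. It was 80 without control replicate 2, 117 without RNAi replicate 3, 1455 without control replicate 3 and 1605 without RNAi replicate 2, and of 83 called genes named for the gut in all texts, 18 passed without control replicate 2 and 24 without RNAi replicate 3.

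Among digestive enzymes, more serine protease genes fell than rose. Of 29 serine proteases of digestion, 14 fell and 2 rose (18 and 3 adjusted over the list alone, 20 and 2 after median centring), with thetaTry at -0.98 and Jon65Aiv, among the most abundant transcripts, going from 18260 ± 2900 to 9235 ± 520 FPKM (log2 fold change -0.97). The list passed with camera (adjusted p = 8.69e-17; adjusted p = 0.371 with an estimated correlation). Of 16 other digestive and neutral lipases, 6 fell and 2 rose (6 and 4 adjusted over the list alone, 7 and 0 after median centring), with a median of -0.02. Those that fell included mag, a lipase secreted into the gut lumen, at -1.31, CG2772 at -0.85, bmm, the fly homologue of adipose triglyceride lipase, at -0.72, and CG3635 at -0.54 (camera adjusted p = 0.000523; adjusted p = 0.302 with an estimated correlation). Carbohydrate digestion went the other way for 7 of 20 genes, with 1 lower, in either scaling and adjusted over the list alone. The maltase genes Mal-A2 and Mal-A8 rose by 1.10 and 1.75 and Amy-p, an amylase gene with a near-identical copy, by 0.87; this list did not pass with camera (adjusted p = 0.709).

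Subunits of oxidative phosphorylation fell as a group. Of 46 genes, 28 fell and 0 rose (35 and 0 adjusted over the list alone), all 46 lay below the median shift, and all 46 were called lower after median centring. The changes were small, with a median of -0.29, and UQCR-14 (-0.50), COX7C (-0.41), ATPsynO (-0.41) and SdhC (-0.40) as examples (camera adjusted p = 2.63e-31; adjusted p = 0.167 with an estimated correlation).

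Some markers of progenitor cells, which comprise the intestinal stem cells and their undifferentiated daughters, were higher. Of 12 markers, 7 rose and 0 fell (8 and 0 adjusted over the list alone, 3 and 0 after median centring). The stem and progenitor factors esg, Sox21a and Sox100B rose by 0.89, 1.42 and 1.17, and the Notch target E(spl)mbeta-HLH by 1.15, although the last was not called after centring (camera adjusted p = 0.0139; adjusted p = 0.481 with an estimated correlation). Among 38 genes of the cell cycle and mitosis, 10 rose and 0 fell (5 and 0 adjusted over the list alone, 3 and 0 after centring). Only 10 of the 38 reached the filter in the libraries with osk, an egg chamber transcript, under 5 FPKM, which are described below. RnrS, a subunit of ribonucleotide reductase, rose by 1.11, geminin by 0.94, scra, the anillin gene, by 1.44 and CycD by 0.71, of which CycD was not called after centring (camera adjusted p = 0.0134; adjusted p = 0.776 with an estimated correlation). Of 19 genes of DNA damage and apoptosis, 10 rose and 0 fell (12 and 0 adjusted over the list alone, 3 and 1 after centring). These included the Ku subunit genes Irbp at 1.30 and Ku80 at 1.26, the checkpoint kinase gene grp at 0.88 and the caspase gene Drice at 0.62, the last not called after centring (camera adjusted p = 0.0548). Of 10 JAK-STAT ligands and targets, 4 rose and 0 fell (7 and 0 adjusted over the list alone). These were the cytokine gene upd3 (1.23), Socs36E (0.76), the receptor gene dome (0.52) and Ptp61F (0.42), and 0 of the 10 were called with limma after centring (3 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.0797).

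Egg chamber transcripts differed between libraries of the same group. FPKM of osk, chosen after its values were seen, was 8.17, 1.09 and 0.0188 in the controls and 22.9, 0.406 and 9.53 in the RNAi guts, and that of the mitotic cyclin gene CycB, chosen in the same way, was 15.8, 0.713 and 0.0733 against 63.3, 2.04 and 30.4. Neither was called (log2 fold change 1.39, adjusted p = 0.36, and 2.54, adjusted p = 0.177). Of 9 genes of the egg chamber and ovary, 0 were called with limma (0 adjusted over the list alone, 0 after centring; 0 at an unadjusted p under 0.05 in either scaling). The median was 0.99, with Cp15 at 1.72 (adjusted p = 0.124), nos at 1.04 (adjusted p = 0.297), piwi at 0.99 (adjusted p = 0.126) and aub at 0.92 (adjusted p = 0.111), while camera gave a downward direction (adjusted p = 0.474). In the 3 libraries with osk under 5 FPKM, 2 controls and 1 RNAi library, as chosen after the data were seen, the median of all genes was 0.28. There the medians were 0.78 for 11 progenitor markers, 0.81 for the 10 of 38 cell cycle genes that reached the filter, 0.56 for DNA damage and apoptosis and 0.70 for JAK-STAT.

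Markers of other cell types were not higher alike. Of 20 markers of enteroendocrine cells, the hormone-producing cells of the gut, 3 fell and 2 rose (3 and 1 adjusted over the list alone, 10 and 0 after centring), with the peptide hormone genes AstA at -1.01, AstC at -0.91 and Dh31 at -0.71 lower and NPF at 0.66 higher, the last not called after centring (camera adjusted p = 7.51e-05; adjusted p = 0.371 with an estimated correlation). Enterocyte markers, 15 genes, had 3 higher and 2 lower (3 and 2 adjusted over the list alone, 0 and 7 after centring), and visceral muscle genes, 22 in number, had 1 higher and 1 lower (1 and 1 adjusted over the list alone, 0 and 2 after centring). Of 8 genes of the fat body and yolk, 2 fell and 0 rose (2 and 0 adjusted over the list alone, 5 and 0 after centring), the yolk protein gene Yp3 at -1.15 and apolpp at -1.18, with Yp2 at -0.77 (adjusted p = 0.0778) and to at -0.33 (adjusted p = 0.0892; camera adjusted p = 7.51e-05; adjusted p = 0.371 with an estimated correlation). Of 11 hemocyte markers, 0 were called with limma (0 adjusted over the list alone; 2 lower and 0 higher at an unadjusted p under 0.05), and 2 were lower after centring (camera adjusted p = 0.000248; adjusted p = 0.481 with an estimated correlation). Of 24 listed Malpighian tubule markers, 20 reached the filter although the tubules were taken off, and carry-over of tubule tissue was not tested. Of these, 3 rose and 1 fell (3 and 1 adjusted over the list alone, 0 and 4 after centring). For this list camera gave a downward direction (adjusted p = 0.0139, and adjusted p = 0.426 with an estimated correlation). Median log2 fold changes were 0.65 for progenitor markers, -0.12 for enteroendocrine markers, -0.17 for enterocyte markers, -0.09 for visceral muscle, -0.51 for fat body and yolk, -0.29 for hemocyte markers and 0.04 for Malpighian tubule markers.

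Genes of stress and defence changed in both directions. Of 29 glutathione S-transferases, 13 rose and 2 fell (13 and 2 adjusted over the list alone, 8 and 3 after centring), with GstD5 at 2.10, GstD8 at 1.88, GstD9 at 1.82 and GstE11 at 1.51 (camera adjusted p = 0.404). Of 10 heat shock proteins, 5 rose and 1 fell (6 and 1 adjusted over the list alone, 2 and 1 after centring). Hsp26 rose by 2.21, Hsp23 by 1.72 and DnaJ-1 by 1.05, the last not called after centring (camera adjusted p = 0.647). Among 13 antimicrobial peptides, DptA and Drsl3 (2.20) were called higher and none lower (1 and 0 adjusted over the list alone, 1 and 0 after centring, where Drsl3 was not called). AttC stood at 1.62 (adjusted p = 0.0916) and Dro at 0.95 (adjusted p = 0.176). The median of the antimicrobial list was 0.51 while camera gave a downward direction (adjusted p = 0.431). In the IMD pathway, which controls these peptides, 5 of 20 genes rose and 3 fell (6 and 3 adjusted over the list alone, 0 and 4 after centring). Those that fell were known dampers of the pathway, PGRP-SC1b, PGRP-SC2 at -1.24 and pirk at -1.05, while the kinase gene IKKbeta stood at 0.44 (adjusted p = 0.0182) and was not called after centring (camera adjusted p = 0.0685).

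**Figure D2:**
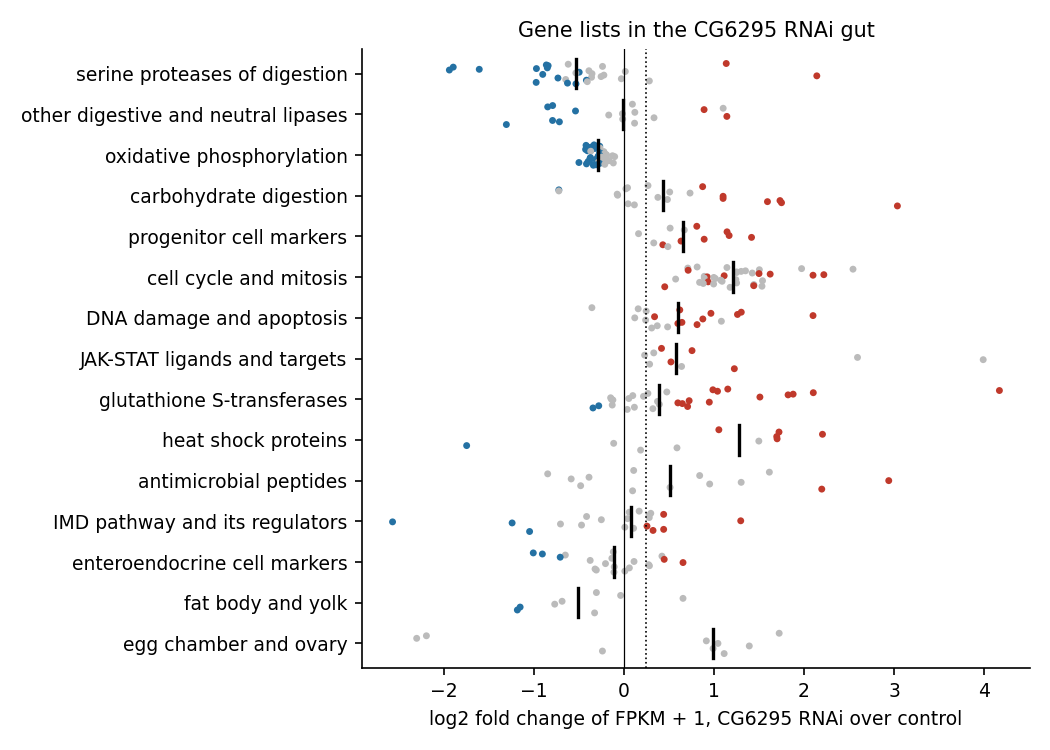
Log2 fold change (log2 of FPKM + 1, CG6295 RNAi over control) of each tested member of 15 gene lists; red and blue dots passed an adjusted p of 0.05 higher or lower, grey dots did not, black bars are medians and the dotted line is the median of all tested genes, 0.25. Oxidative phosphorylation lies below that line for all 46 members. The cell cycle list has a median of 1.21, but only 10 of its 38 members reached the filter in the libraries with osk under 5 FPKM.

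Liph was low in IEC-6 cells and lower with each hairpin. The controls held 0.169, 0.246 and 0.272 FPKM (mean 0.229 ± 0.0534, SD, n = 3), the sh1 libraries 0.0136, 0.00908 and 0.112 (0.0449 ± 0.0582), and the sh2 libraries 0.0361, 0.0241 and 0.0164 (0.0256 ± 0.00991). Means were 19.6% and 11.2% of control. The values correspond to at least 39, 60 and 64 reads in the controls, 3, 2 and 27 with sh1 and 9, 6 and 4 with sh2. The related lipase gene Lipg, not targeted, had at least 10, 19 and 20 reads in the controls. It had 2, 2 and 12 with sh1 and 4, 9 and 2 with sh2. Lipc had at least 13, 4 and 4 reads in the controls, 1, 2 and 3 with sh1 and 2, 1 and 0 with sh2. These values of Lipg and Lipc rest on few reads, and Lipg in sh1 replicate 3 (0.185 FPKM) stood above control replicate 1 (0.161 FPKM). Whether lower values with the hairpins were particular to Liph was not tested. On the log2(FPKM + 1) scale, which compresses values this low, the changes were -0.23 (limma adjusted p = 0.163) for sh1 and -0.26 (adjusted p = 0.0824) for sh2, and neither passed. The exact permutation test gave p = 0.1 for each hairpin, the smallest value possible. With a pseudocount of 0.1 the changes were -1.24 (adjusted p = 0.0919) and -1.38 (adjusted p = 0.0362), and the sh2 change passed. In sh1 replicate 3, Liph remained at 0.112 FPKM, so that this library was the least lowered of the 6.

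With Liph sh1, most listed interferon response genes fell, as did some of the genes of cholesterol synthesis and some fibroblast and mesenchymal markers, while some epithelial markers rose. Of 30 interferon response genes, 20 fell and 0 rose (24 and 1 adjusted over the list alone, 20 and 0 after median centring), with a median of -1.15. Ifih1, a sensor of double-stranded RNA, fell by 0.76, Oasl by 1.40 and the signal transducer gene Stat2 by 1.13 on the log2 scale, while Psmb8 stood at 0.39 (adjusted p = 0.104). Mx2 at -3.46, Oas1a at -2.87 and Isg15 at -2.54 were chosen after their values were seen. The list passed with camera (adjusted p = 1.66e-16; adjusted p = 0.716 with an estimated correlation). Of 24 genes of cholesterol synthesis, 8 fell and 0 rose (17 and 0 adjusted over the list alone, 10 and 0 after centring), among them Nsdhl (-1.04) and Hsd17b7 (-0.96). Insig1 (-0.51, adjusted p = 0.0707) did not pass (camera adjusted p = 2.4e-10; adjusted p = 0.716 with an estimated correlation). Of 15 intestinal epithelial cell markers, 5 rose and 0 fell (9 and 1 adjusted over the list alone, 5 and 0 after centring), including Krt19, an epithelial keratin (1.5), the microvillus gene Vil1 (1.15) and Bmi1 (0.55), with Hnf4a at 0.51 (adjusted p = 0.081; camera adjusted p = 0.00562; adjusted p = 0.716 with an estimated correlation). Of 22 fibroblast and mesenchymal markers, 4 fell and 0 rose (7 and 0 adjusted over the list alone, 4 and 0 after centring), with a median of -0.40. Col5a1 fell by 0.68 and Twist2 by 0.54. Col1a1 at -1.49 and Fbn1 at -1.20 were chosen after their values were seen. Sparc at -0.58 (adjusted p = 0.0543) and Col5a2 at -0.74 (adjusted p = 0.0903) did not pass (camera adjusted p = 0.00339; adjusted p = 0.716 with an estimated correlation).

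Fewer proliferation genes passed with sh1. Of 30 DNA replication genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone, 6 and 0 after centring), with a median of -0.22 (camera adjusted p = 0.000155; adjusted p = 0.716 with an estimated correlation). Of 33 mitosis genes, 0 passed with limma (0 adjusted over the list alone, 0 after centring; 8 lower and 0 higher at an unadjusted p under 0.05), and the median was -0.42 (camera adjusted p = 5.56e-06; adjusted p = 0.716 with an estimated correlation). DNA repair had 3 of 29 lower (3 adjusted over the list alone, 3 after centring; camera adjusted p = 0.0186; adjusted p = 0.716 with an estimated correlation). Of 31 genes of autophagy and the lysosome, 4 rose (8 adjusted over the list alone, 3 after centring; camera adjusted p = 0.00562). Of 23 p53 targets, 2 rose (2 adjusted over the list alone, 2 after centring; camera adjusted p = 0.00844). The adjusted p was 0.716 for both with an estimated correlation. The sh1 comparison called 1336 of 10638 genes, 732 higher and 604 lower, and after median centring 1299, 577 higher and 722 lower. That count was 260 without control replicate 2, 328 without control replicate 1, 578 without sh1 replicate 1 and 2264 without sh1 replicate 2, and 287 when only sh1 and control were fitted.

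With Liph sh2, nearly all listed genes of DNA replication and mitosis fell, as did most of those of DNA repair. Of 30 DNA replication genes, 29 fell and 0 rose (30 and 0 adjusted over the list alone, 28 and 0 after centring), with a median of -1.07. The helicase subunit gene Mcm6 fell from 104.0 ± 8.44 to 44.6 ± 1.69 FPKM (log2 fold change -1.20), and Pole, Gins2 and E2f1 fell by 1.02, 0.76 and 0.65. Of 33 mitosis genes, 32 fell and 0 rose (33 and 0 adjusted over the list alone, 31 and 0 after centring), with Plk1, a mitotic kinase, at -1.63, Kif23 at -1.23, Tacc3 at -1.10 and Cenpf at -1.0. Of 29 DNA repair genes, 23 fell and 1 rose (24 and 2 adjusted over the list alone, 21 and 2 after centring), with Parp1 at -2.35, Fanci at -1.35, the RecQ helicase gene Blm at -1.21 and the kinase gene Atm at -0.76. The camera adjusted p-values of these lists were 1.06e-13, 1.42e-10 and 1.86e-07, and adjusted p = 0.605, 0.726 and 0.589 with an estimated correlation.

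Most listed genes of autophagy and the lysosome and some p53 targets rose with sh2. Of 31 genes of autophagy and the lysosome, 21 rose and 1 fell (22 and 2 adjusted over the list alone, 23 and 0 after centring), among them Lamp2 at 0.72, Atg12 at 0.59, Ctsl, the cathepsin L gene, at 0.52 and Wipi2 at 0.46 (camera adjusted p = 1.53e-09; adjusted p = 0.719 with an estimated correlation). Of 23 p53 targets, 11 rose and 2 fell (12 and 2 adjusted over the list alone, 14 and 2 after centring). The cyclin-dependent kinase inhibitor gene Cdkn1a rose from 7.34 ± 0.461 to 33.7 ± 1.90 FPKM (log2 fold change 2.06), Btg2 by 1.18, Mdm2 by 0.98 and Zmat3 by 0.83 (camera adjusted p = 0.000139; adjusted p = 0.589 with an estimated correlation). Of 24 genes of cholesterol synthesis, 7 fell and 0 rose (5 and 0 adjusted over the list alone, 4 and 0 after centring). Insig1 fell by 1.61, Nsdhl by 0.68 and Hsd17b7 by 0.58, and Nsdhl and Hsd17b7 were not called after centring. The list did not pass (camera adjusted p = 0.178). Of 15 epithelial markers, 6 fell and 0 rose (6 and 0 adjusted over the list alone, 4 and 0 after centring; camera adjusted p = 0.14). Of 30 interferon response genes, 3 rose and 2 fell (3 and 0 adjusted over the list alone, 5 and 1 after centring; camera adjusted p = 0.396). Of 22 fibroblast and mesenchymal markers, 4 rose and 4 fell (4 and 4 adjusted over the list alone, 4 and 2 after centring; camera adjusted p = 0.308), with Sparc at 1.29, Col5a2 at 1.02, Col5a1 at 0.90 and Twist2 at -0.67. The sh2 comparison called 3825 of 10638 genes, 1441 higher and 2384 lower. After median centring it called 3724, 2024 higher and 1700 lower.

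**Figure D3:**
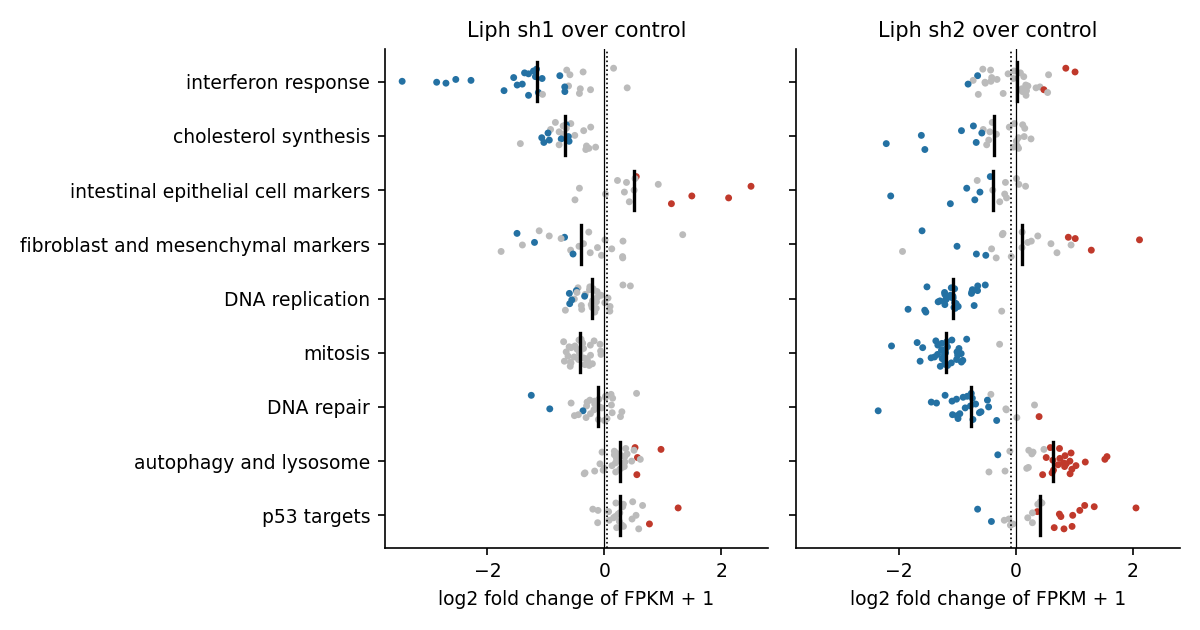
Log2 fold change (log2 of FPKM + 1, hairpin over control) of each tested member of 9 gene lists in IEC-6 cells, sh1 on the left and sh2 on the right; red and blue dots passed an adjusted p of 0.05 higher or lower, grey dots did not, black bars are medians and the dotted line is the median of all tested genes. Interferon response genes have a median of -1.15 with sh1, and mitosis genes a median of -1.20 with sh2.

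The genes that changed the same way with both hairpins included the keratin genes Krt23 and Krt80, MHC class I genes and the cell cycle inhibitor Cdkn1a. Another keratin gene, Krt19, was called in opposite directions (1.5 with sh1 and -2.14 with sh2). Higher with both were S100g, a calcium-binding protein gene (log2 fold change 1.88 with sh1 and 2.40 with sh2), Krt23 (1.76 and 2.73), Cyp3a9 (2.81 and 1.58), Olr1, a receptor of oxidised lipoprotein (1.96 and 1.5), Cdkn1a (1.26 and 2.06), and Gpnmb (1.21 and 1.16). Tcn2, Krt80, Smpdl3a and Cryab followed, at 1.07 to 1.11 with sh1 and 1.34 to 2.10 with sh2. The sh1 call of Cryab was lost after centring (adjusted p = 0.0561). Lower with both were Anxa8 (-1.87 and -2.56), Vsig1 (-2.41 and -1.60), the interferon-induced chemokine gene Cxcl10 (-1.49 and -1.53), Timd2 (-2.79 and -1.39), the MHC class I genes RT1-N3 (-1.27 and -1.26) and RT1-T24-4 (-1.16 and -1.47), and Blm (-1.25 and -1.21). B4galnt4 (-0.92 and -0.91), Gpd1l (-0.93 and -0.91) and Anp32b (-1.68 and -0.84) were the remaining 3. MHC class I genes are a family of similar sequences, which could share reads.

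In all, 236 genes were called the same way with both hairpins, 118 higher and 118 lower, where independent lists of these sizes would give 99.2 and 135.4. Another 269 were called in opposite directions, 132 higher with sh1 and lower with sh2 and 137 the reverse, where independent lists would give 164 and 81.8. The opposite calls numbered 48, 40 and 167 without control replicates 1, 2 and 3, 133, 511 and 285 without sh1 replicates 1, 2 and 3, and 112, 175 and 154 without sh2 replicates 1, 2 and 3. Across genes, which are not independent replicates, the fold changes of the hairpins had a correlation of 0.038, against 0.50 in simulations of unchanged groups that share the control libraries. In the data 48.9% of genes had the same sign, against 66.7% simulated. The simulations hold no effect of a hairpin, so their correlation and share of signs are not like for like with the data. The covariance of the fold changes was 0.008 against 0.014 simulated. Without sh1 replicate 1 it was -0.009, where the shared controls would give 0.011, and without sh1 replicate 3 it was 0.021, where they would give 0.012. Its side of the value from shared controls thus depended on single libraries. The count of 236 was 46, 73 and 135 without control replicates 2, 1 and 3, 146, 520 and 351 without sh1 replicates 1, 2 and 3, and 93, 148 and 136 without sh2 replicates 1, 2 and 3. Both hairpins were compared with the same 3 control libraries.

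The hairpins were also compared with each other, and 5449 of 10638 genes were called, 1896 higher and 3553 lower with sh2. The median gene was lower by 0.15 on the log2 scale, and after centring 5037 were called, 2624 higher and 2413 lower. Higher with sh2 were Hpx, the gene of the haem-binding plasma protein hemopexin (219.1 ± 8.10 against 5.52 ± 1.39 FPKM, log2 fold change 5.10), Fetub (4.63), Arhgef26 (3.70), Wfdc21 (3.66) and the mitochondrial creatine kinase gene Ckmt1 (3.27). Higher with sh1 were the mucin gene Muc5b (51.2 ± 41.2 against 0.579 ± 0.143 FPKM, log2 fold change -4.76), Tesc (-4.21), Fgf19 (-3.93), Krt19 (-3.63) and Scgb1a1 (-3.58). Interferon response genes were higher with sh2 than with sh1 in 22 of 30 cases and lower in 0 (22 and 0 adjusted over the list alone, 24 and 0 after centring; camera adjusted p = 1.25e-10; adjusted p = 0.739 with an estimated correlation). DNA replication genes were lower with sh2 in 26 of 30 cases and epithelial markers in 10 of 15 (28 and 11 adjusted over the list alone, 24 and 9 after centring), with camera adjusted p-values of 4.96e-07 and 0.00454, and adjusted p = 0.739 for each with an estimated correlation.

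**Figure D4:**
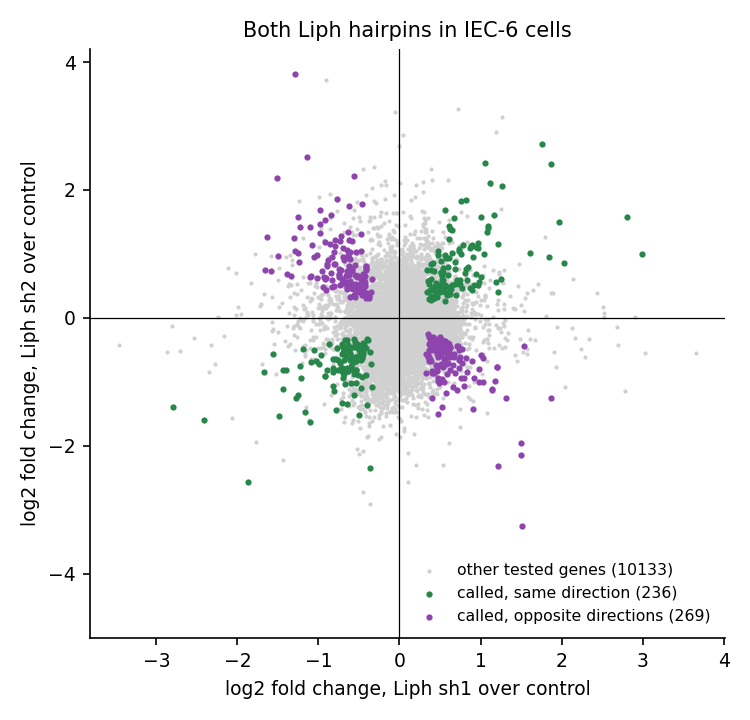
Log2 fold change (log2 of FPKM + 1) of 10638 genes with Liph sh1 (horizontal axis) and Liph sh2 (vertical axis) over the same controls; green dots are the 236 genes called the same way with both, purple dots the 269 called in opposite directions, and grey dots the other tested genes. Purple dots in the upper left are the 137 genes lower with sh1 and higher with sh2.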

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

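The differences given here between the effects of the Liph hairpins were tested directly, by the limma contrast of sh2 against sh1 planned at the outset; the tests of explanations and the splits of the libraries were chosen only after the results were seen. All values are log2 fold changes of sh2 over sh1, for genes whose change against control differed between the hairpins.

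Among genes called the same way with both hairpins, the size of the change differed for Cyp3a9 (-1.23), Cdkn1a (0.80), Tcn2 (0.99), Vsig1 (0.81), Timd2 (1.41) and Anp32b (0.84). The largest differences in either direction were in Hpx (5.10), Fetub (4.63), Arhgef26 (3.70), Wfdc21 (3.66), Ckmt1 (3.27), Muc5b (-4.76), Tesc (-4.21), Fgf19 (-3.93), Krt19 (-3.63) and Scgb1a1 (-3.58).

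The interferon response genes Stat2 (1.67), Mx2 (3.04), Oas1a (2.34) and Isg15 (2.22) were higher with sh2 than with sh1, and the median of that list was 1.15 (22 higher and 0 lower; camera adjusted p = 1.25e-10). The median was -0.87 for DNA replication (0 higher and 26 lower; 4.96e-07), with Mcm6 at -0.64, and -0.78 for mitosis (0 and 24; 0.000501), with Plk1 at -0.95. DNA repair had a median of -0.64 (1 and 21; 0.00208), with Parp1 at -1.98, Atm at -1.31 and Fanci at -0.79, and p53 targets had a median of 0.25 (8 and 3; 0.0451). Intestinal epithelial markers had a median of -0.88 (0 and 10; 0.00454), with Vil1 at -2.26, Bmi1 at -0.98 and Hnf4a at -0.90. Cholesterol synthesis had a median of 0.36 (6 and 3; 0.0105), while its member Insig1 (-1.11) was lower with sh2. The median was 0.41 for autophagy and the lysosome (18 and 3; 0.000403), with Lamp2 also at 0.41, and 0.34 for the unfolded protein and integrated stress response (13 and 7; 0.0088), with Pdia4 at 1.38. Extracellular matrix genes and TGF-beta targets had a median of 0.38 (13 and 3; 0.00454), with Tgfb3 at 1.71, Tgfbr1 at 1.43, Lamc1 at 1.45 and Loxl2 at 1.52. Fibroblast and mesenchymal markers had a median of 0.30 (9 and 3; 0.0141), with Sparc at 1.87, Col5a2 at 1.76, Col5a1 at 1.58, Fbn1 at 1.40 and Col1a1 at 1.28. None of these lists passed camera with an estimated correlation (adjusted p = 0.739 or above). After median centring the higher and lower counts were 24 and 0 for interferon response, 0 and 24 for DNA replication, 0 and 17 for mitosis, 3 and 16 for DNA repair and 10 and 0 for fibroblast markers. They were 11 and 3 for cholesterol synthesis, 10 and 2 for p53 targets, 0 and 9 for epithelial markers, 18 and 2 for autophagy and the lysosome, 14 and 7 for the unfolded protein response, 13 and 2 for extracellular matrix and 5 and 3 for lysophosphatidic acid signalling. In lysophosphatidic acid signalling, 2 genes were higher and 4 lower before centring, and the list did not pass (camera adjusted p = 0.539). Its members Plpp1 and Lpar1 were at 0.53 and -1.02.

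The hairpins called 269 genes in opposite directions. The loss of Liph alone, as the whole cause, would leave the hairpins closer to each other than to control, since Liph was at 19.6% and 11.2% of control. Yet 5449 genes were called between the hairpins, against 3825 and 1336 between a hairpin and control. With 1 library left out the counts were at least 4243 between the hairpins and at most 3251 for either hairpin and control. In those fits of sh2 against control all sh1 libraries stayed in the estimate of the spread. With only the groups compared in the fit the gap nearly closed, at 4946 genes between the hairpins, 4917 for sh2 and 287 for sh1, though the count between the hairpins was not the lower one. Counts of calls follow the spread in a fit as well as the distance between groups, so they do not decide on that explanation. The count of 269 does not decide either, since calls the same way, 236, outnumbered the opposite ones without 5 of the 9 libraries: 73 to 48 and 46 to 40 without control replicates 1 and 2, and 146 to 133, 520 to 511 and 351 to 285 without sh1 replicates 1, 2 and 3. The opposite calls were 167 without control replicate 3, and 112, 175 and 154 without sh2 replicates 1, 2 and 3. The Liph left in sh1 replicate 3 does not account for all of them, given the 285 without that library. Off-target effects of a hairpin, or other differences between the cell pools, may underlie the 5449 genes called between the hairpins, and cannot be told apart here because the hairpin sequences are not in the sources used here. A biological difference in how far each hairpin lowered lipase H protein was not tested.

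For the count of 236 genes called the same way with both hairpins, 3 of 100 drawn splits of the 9 libraries into groups of 3 gave as many, the real one included. The other 97 all gave 0, so the splits cannot weigh an overlap by chance of 2 long lists of genes, and independent lists of these sizes would give 234.6 genes in all. The 2 larger splits, with 2709 and 3031 genes, both put the 3 sh2 libraries in the place of the controls, which points to a structure of the samples, the distance of sh2 from the other libraries. For each pairwise comparison the libraries allow 10 splits, too few for a share under 0.05, and 1 of 10, the real one, was as large as the real count. The real counts were 1336, 3825 and 5449 for sh1 against control, sh2 against control and sh2 against sh1, and the highest of the other splits gave 3, 0 and 0.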

How the results depend on the processing

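The alternatives were planned, except the count of 781 gut genes called both as deposited and after median centring and the fit of gut libraries with osk under 5 FPKM, both chosen after the data were seen. That fit, with a lone RNAi library assumed to vary like the controls, called 650 genes, 516 higher and 134 lower, and CG6295 at -1.55 lost its call (adjusted p = 0.0519); it holds fewer libraries. With another pseudocount, a filter at 5 FPKM, no filter or moderation without the trend, the 5 counts of genes called stayed within 1.5 times. The gut count of 2540 was 3843 with TPM scaling, 1201 with median centring, 1061 with quantile normalization and 866 with the replicate number as a block. With the block the sh1 count was 676 and the count for both hairpins 119; with only the groups compared in the fit they were 287 and 74. The number in the label does not pair the libraries, since libraries of the same number had correlations from -0.58 to 0.19 between groups. With a log2 fold change of at least 1, counts were 285 in the gut, 255 for sh1, 685 for sh2, 1098 for sh2 against sh1 and 25 for both hairpins, by construction.

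Leaving out 1 library at a time gave 80 to 2433 genes in the gut, 260 to 2264 for sh1, 2570 to 3251 for sh2, 4243 to 5459 for sh2 against sh1 and 46 to 520 for both hairpins. The gut count was 80 without control replicate 2, 117 without RNAi replicate 3, 1455 without control replicate 3 and 1605 without RNAi replicate 2. The sh1 count was 260 without control replicate 2, 328 without control replicate 1, 578 without sh1 replicate 1 and 2264 without sh1 replicate 2. The count for both was 46, 73 and 135 without control replicates 2, 1 and 3, 146 and 520 without sh1 replicates 1 and 2, and 93, 148 and 136 without sh2 replicates 1, 2 and 3. Fewer libraries lower the power, but why single libraries weighed so differently was not tested.

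CG6295 ran from -1.30 to -0.90 with 1 library left out (-1.55 to -0.90 over all alternatives, adjusted p = 0.0126 to 0.0787) and lost its call without control replicate 2 (-1.01) and without RNAi replicate 3 (-1.14). Liph, from -0.28 to -0.21 with sh1 and -0.30 to -0.23 with sh2 with 1 library left out, and from -1.24 to -0.14 and -1.38 to -0.16 over all alternatives, passed without a filter at -0.23 and -0.26 (adjusted p = 0.0271 and 0.00483; 0.0271 to 0.431 and 0.00483 to 0.313 over all alternatives). With sh2 it also passed with a pseudocount of 0.1 (-1.38), TPM scaling (-0.51) and only the groups compared in the fit (-0.26). CG6283 ran from -0.31 to 0.10 with 1 library left out and from -0.50 to 0.10 over all alternatives, changing sign with TPM scaling (0.002) and without RNAi replicate 2 (0.10). Fbn1 with sh2, not called, ran from -0.081 without control replicate 3 to 0.46 without control replicate 2. The causes were not tested. Of 83 gut genes named and called, 67 kept their call with median centring and 55 with the block, and 50 of 82 tested with osk under 5 FPKM. Of 50 for sh1, 20 kept it without control replicate 2 and 22 with only the groups compared in the fit. Of 59 for sh2, 50 to 52 kept it with any 1 library left out, and all 10 named for sh2 against sh1 did. Liph values correspond to as few as 2 reads in a library, as a minimum; whether depth limits its call was not tested, since the absolute depth is unknown.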

Other observations

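Of the tests in this part, the read share of abundant genes was set out before its result was seen, and the depth test, the tests on digestive genes, cell markers and egg chamber transcripts, the splits and the table of heat shock copies were chosen only after the results were seen.

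Members of other gene groups of metabolism and detoxification were called in the CG6295 RNAi guts, although 3 of the 4 lists did not pass with camera. Of 57 cytochromes P450, 16 rose and 6 fell (19 and 6 adjusted over the list alone; 9 and 12 after median centring), with Cyp28a5 at 2.37, Cyp9b2 at 2.03, Cyp309a1 at 1.79 and Cyp6d4 at 0.89 (log2 fold change; camera adjusted p = 0.0586). Of 21 genes of insulin and TOR signalling, 8 rose and 0 fell (8 and 0 adjusted over the list alone; 3 and 0 after centring), among them tobi, the TOR inhibitor gene chrb at 1.00, Lst8 at 0.57, and Tsc1 at 0.39, the last not called after centring (camera adjusted p = 0.162). Of 23 genes of autophagy and the lysosome, 8 rose and 0 fell (8 and 0 adjusted over the list alone; 1 and 1 after centring), with Atg1 at 0.72 and, not called after centring, Atg18a at 0.58, ref(2)P at 0.51 and Atg7 at 0.38 (camera adjusted p = 0.742). Of 18 genes of fatty acid oxidation, 3 fell and 2 rose (3 and 2 adjusted over the list alone; 10 and 0 after centring), with CG9527 at -0.62, Etf-QO at -0.58 and Thiolase at -0.30, and CG5844 at 0.45, the last not called after centring (camera adjusted p = 7.51e-05; adjusted p = 0.481 with an estimated correlation). The near-identical copies of Hsp70 went from 0.168 to 1.30 FPKM for Hsp70Aa, 0.498 to 3.89 for Hsp70Ab, 1.78 to 1.67 for Hsp70Ba, 99.9 to 29.9 for Hsp70Bb and 0.170 to 0.614 for Hsp70Bbb.

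In IEC-6 cells, genes of lysophosphatidic acid signalling, the lipid that lipase H is known to produce, changed in small numbers. Of 13 genes, 3 rose and 2 fell with sh1, and 2 rose and 2 fell with sh2 (the same counts adjusted over the list alone; 3 and 2, and 5 and 0, after centring). Plpp2, a lipid phosphate phosphatase gene, fell by 0.45 and by 0.39, the latter not called after centring (adjusted p = 0.126), the receptor gene Lpar1 stood at 0.75 with sh1 and -0.27 (adjusted p = 0.177) with sh2, and Agpat3 at 0.19 (adjusted p = 0.287) and 0.36. Of 29 genes of the unfolded protein and integrated stress response, 5 rose and 8 fell with sh1 (7 and 11 adjusted over the list alone; 5 and 9 after centring), and 12 rose and 6 fell with sh2 (16 and 7 adjusted over the list alone; 16 and 4 after centring; camera adjusted p = 0.0168; adjusted p = 0.589 with an estimated correlation). Hyou1 fell by 0.82 and 0.78, Creld2 fell by 0.82 and 0.64, and Ddit3, a stress-induced transcription factor gene, rose by 0.82 and 0.77. Of 26 extracellular matrix genes and TGF-beta targets, 1 rose and 2 fell with sh1 (5 and 6 adjusted over the list alone; 0 and 4 after centring) and 11 rose and 2 fell with sh2 (12 and 2 adjusted over the list alone; 12 and 2 after centring; camera adjusted p = 0.00055; adjusted p = 0.726 with an estimated correlation).

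More genes were called higher than lower in the RNAi guts, with a median shift of 0.25 on the log2 scale. Mean depth of the RNAi libraries exceeded that of the controls by 0.28%. FPKM are already scaled to the size of the library, so the depth test cannot decide on the cause of the shift. The 50 genes with most reads took 32.2% ± 1.22 of reads in the controls and 26.6% ± 1.51 in the RNAi guts (SD, n = 3 each), which alone would raise all other genes by 0.115 (0.052 to 0.16 over pairs of libraries). That may account for part of the shift. A uniform change in total RNA per gut would not show in FPKM, and no spike-in to measure it is reported in the sources used here. The gut libraries allow 10 splits, too few for a share under 0.05; 1 of 10, the real one, gave 2540 genes, and the highest of the others gave 17.

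Some digestive genes fell in the RNAi guts, and 7 of 12 progenitor markers rose. A smaller share of enterocytes would raise markers of every other cell type alike. The median of the progenitor markers exceeded that of the enteroendocrine markers by 0.77 (bootstrap SE 0.173, 2000 draws of marker genes). The draws were of genes, not of libraries, so the SE does not measure the spread between guts. The difference therefore does not decide on the share of enterocytes. Of 46 other digestive enzyme genes with at least 100 FPKM in the controls, 18 were called lower, and 4 fell by as much as CG6295: Jon65Aii, Jon66Ci (-1.61), Jon66Cii and mag. The fall of CG6295 could therefore reflect a wider fall of digestive genes as well as the RNAi. Egg chamber tissue carried over with the guts, or a larger number of progenitor cells, may underlie the higher markers: the progenitor median was 0.78 in the 3 libraries with osk under 5 FPKM, but only 1 of these is an RNAi library, too few to decide.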
